A study of Homo sapiens with 2 samples.

How the data were processed

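Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on HEK293 cells, an established human embryonic kidney line. WRN is the RecQ-family helicase and exonuclease that is lost in Werner syndrome. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 minutes, and chromatin was sheared to fragments of about 500 bp. One library was made with an antibody against WRN and 1 with a control antibody, labelled as a non-specific IgG. Per the labels' protocols, this control was a rabbit antibody raised against fatty acid synthase. There was 1 library per group and therefore no replicate. The groups were taken from the antibody label. The source names of the 2 libraries are the other way round from their titles and antibody labels. The series title speaks of S phase, but the growth and treatment labels describe no synchronisation step.

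The data used were 1 deposited peak list for the series, with a position, a name and a score per peak. The peaks were called with MACS, per the names in the deposited file. Its version, its settings and the use of the control library as background are not given in the sources used here. Per the submitters' processing notes, reads were trimmed with cutadapt 1.2.1 and TopHat2 2.0.10 was used, with the hg19 genome build. TopHat2 is a splice-aware aligner made for RNA. How it was set to treat reads that match several places is not given in the sources used here. The score is the authors' own peak score, as deposited, and was compared only between peaks within this list, by rank, by class medians and for equal values. Differences in score are in its own units and are not measures of binding strength. The lowest score was 50.03 and 1 peak stood at exactly 3100. Such a floor and ceiling would arise from a score proportional to the logarithm of a p-value, but no header states the scale. No read counts or read depth were given, so the depth behind each peak is unknown and no fold over the control library was computed. No peak list of the control library was used here. All intervals below cover counting error only, and peaks are not replicates.

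All positions are hg19 and 1-based. No hg19 gene annotation or genome sequence was used here. The planned tests of overlap with single tRNA genes, transcription start sites, gene bodies and the fixed gene lists were therefore not run. Those lists covered other RNA polymerase III genes, snRNA, histone, ribosomal protein, DNA replication, double-strand break and RecQ, respiratory chain, fragile site and olfactory receptor or keratin-associated genes. The planned tests of GC content and G-quadruplex motifs were not run either. In their place stood the fallback fixed before the data were examined, 8 windows with 15 Mb in total known to hold clusters of tRNA genes. All other fixed choices named below were also made before the data were examined, unless stated otherwise. The bands and CpG islands were chosen as coarse stand-ins for GC-rich DNA after the data were examined. The hg19 chromosome lengths came from GenomeInfoDb 1.38.1 and the hg19 cytogenetic bands from circlize 0.4.16. CpG islands were at hand for chromosomes X and Y only, from pyranges 0.1.4. Their build is not named there, but the last island of Y lies beyond the end of that chromosome in GRCh38. The gene table of GRCh38.p14 was used only for gene names and for which genes neighbour each other. A tRNA cluster in it was a run of tRNA genes with at most 10 protein-coding genes between neighbours.

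For each region class, the number of peaks was compared with 1000 random placements of the peaks on their own chromosomes, outside centromeric, heterochromatic and stalk bands, which stood in for assembly gaps. A peak counted as in a window with at least 1 bp of overlap. A peak counted as near a chromosome end when its midpoint lay within 1 Mb of it. The resulting empirical p is called a permutation p below. The tests of windows and islands were one-sided, and those of ends and bands two-sided. The smallest p the placements can give is 0.001 one-sided and 0.002 two-sided. Benjamini-Hochberg adjustment was made over the 8 windows. Peaks per chromosome were compared with chromosome length by exact two-sided binomial tests, adjusted over 24 chromosomes. Scores were compared between classes by a two-sided permutation test of the difference in medians with 100000 resamples, adjusted over 3 classes. Of these, the ends and the pale bands were added after the data were examined. Shares carry exact 95% Clopper-Pearson intervals. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 20 peaks with the highest score were named by a fixed rule. The highest-scoring peak of each window was named as well, which was not part of that rule.

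The procedures were tested on simulated data. Of 200 sets of 1338 randomly placed peaks, 9 passed the threshold of 0.05 for the windows, 5 for the ends and 16 for the pale bands. The simulated peaks were placed independently, by the same procedure as the placements. These sets therefore do not cover clustered peaks, for which the permutation p can be too small. With 100 peaks moved into the windows, an excess of 105.2 was recovered. Alternatives were the 669 peaks that scored above the median, placement anywhere on the chromosomes, merging of peaks within 1 kb, and leaving out the chromosome with the most peaks per Mb. Further alternatives were leaving out the 6p22 window, a distance of 5 Mb for the ends and permutation within 4 strata of peak width. Others were added after the data were examined. The 2 peaks on sequences outside the assembled chromosomes were left out of all comparisons.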

Results

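The deposited list held 1340 peaks for WRN in HEK293 cells. Of these, 1338 lay on assembled chromosomes and 2 on sequences outside them. The peaks were short, with a median width of 902 bp, quartiles of 717 and 1216 bp and a range from 267 to 11706 bp. Together they covered 1486 kb, or 0.0479% of the assembled length. Scores had a median of 70.5 and quartiles of 56.2 and 113. A score over 100 was reached by 408 peaks, over 500 by 24 and over 1000 by 7. With 1 anti-WRN library and 1 control library there was no replicate, the read depth is unknown, and every comparison below is between places in the genome within this 1 list.

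The peaks were not spread evenly. On average there were 0.432 peaks per Mb, but 2294 of 3113 bins of 1 Mb held none and 9 held 10 or more. Random placement put at most 8 peaks in any bin in 1000 placements, with a median of 5 for the fullest bin. Of the 9 bins with 10 or more peaks, 7 lay in the tRNA cluster windows. The other 2 lay on chromosome 8 from 30 to 31 Mb, with 11 peaks, and on chromosome 7 from 157 to 158 Mb, with 10. Neighbouring peaks were often close: 105 began within 10 kb of the end of the one before, against a mean of 7.88 and a highest value of 19 under random placement.

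**Figure D1:**
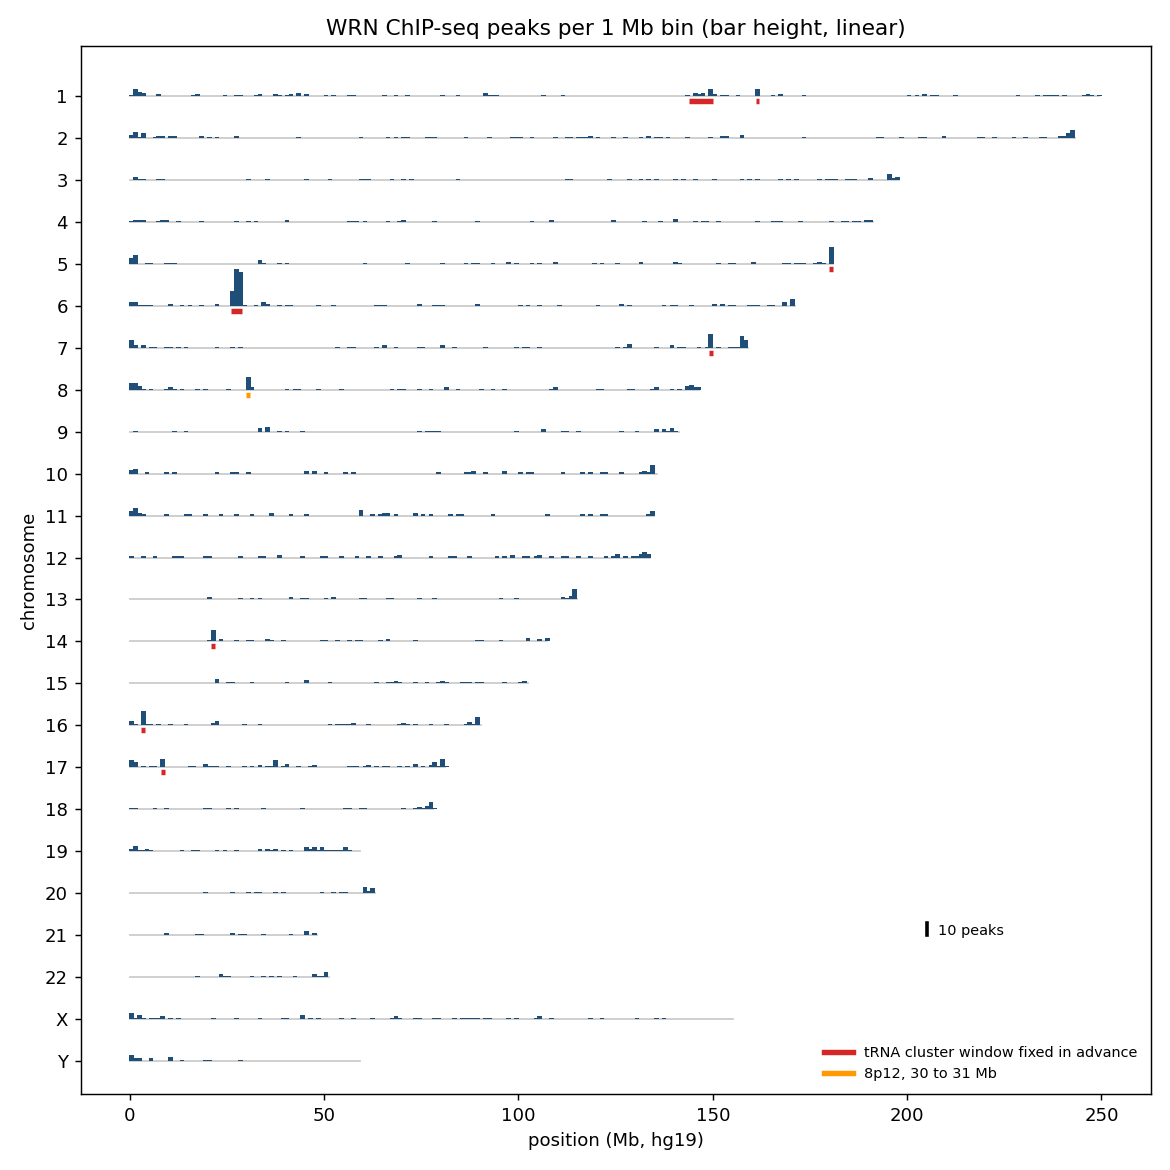
Peaks per 1 Mb bin (bar height, linear, with a scale bar of 10 peaks) along the 24 chromosomes, with position in Mb of hg19 on the x axis. Red marks are the 8 tRNA cluster windows and the orange mark is 8p12 from 30 to 31 Mb; the highest bars, of 31 and 29 peaks, stand in the 6p22 window on chromosome 6.

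The series title names tRNA genes, which are transcribed by RNA polymerase III and stand largely in clusters, and the first comparison asked whether peaks gathered where those clusters lie. The 8 windows held 148 of the 1338 peaks, or 11.1% (95% interval 9.43 to 12.9). Random placement put 8.78 peaks there on average and never more than 18, a 16.9-fold excess (one-sided random-placement permutation p = 0.001, the smallest the placements can give). The 6p22 window, from 26 to 29 Mb of chromosome 6, held 73 of them. This is the region of the largest human tRNA gene cluster, which also holds most replication-dependent histone genes. Without this window the others still held 75 peaks, a 12.02-fold excess. With placement matched on band stain, the excess over all windows was 10.7-fold. Because the windows are 1 to 6 Mb long and hold other genes too, this count does not show which gene a peak lies at.

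Each window taken alone held more peaks than any of the 1000 placements (adjusted permutation p = 0.001 for each). The 6p22 window had 73 peaks against 2.55 by placement, and its 3 bins held 13, 31 and 29. The window at 5q35, from 180 Mb to the chromosome end, had 14 peaks against 0.389, and that at 7q36, the 1 Mb up to 150 Mb, had 12 against 0.536. The 14q11 window, from 21 to 22 Mb, had 10 against 0.469. The 16p13 window, from 3 to 4 Mb, had 12 against 0.705. The 1 Mb window at 1q23 had 6 against 0.461, and the 17p13 window, from 8 to 9 Mb, had 7 against 1.05. The lowest ratio, 5.35-fold, was in the 6 Mb window at 1q21, up to 150 Mb, with 14 peaks against 2.62. Flanks of equal width on both sides of the windows held 9 peaks in all, of which 5 flanked the 1q21 window. The 5q35 window runs to the chromosome end and has a left flank only.

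**Figure D2:**
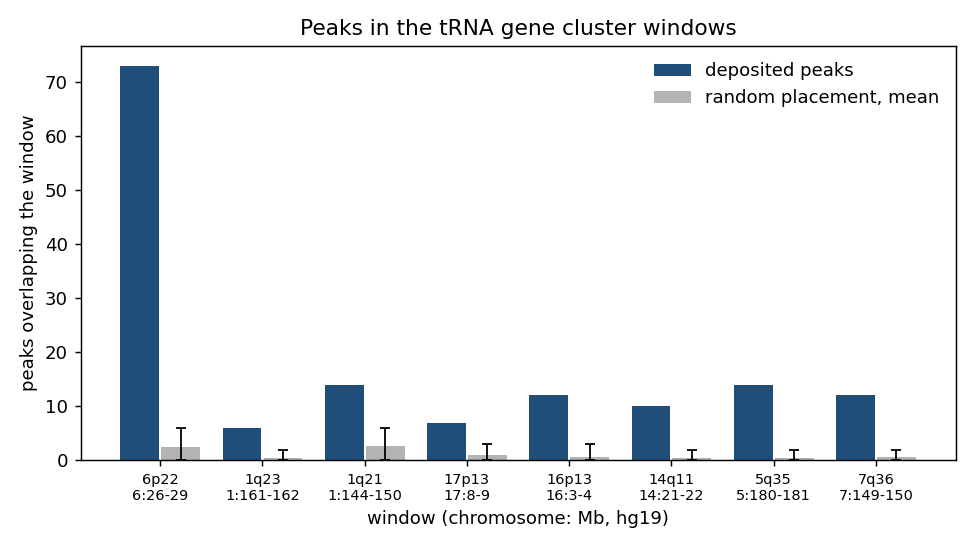
Number of deposited peaks overlapping each tRNA cluster window (dark bars) and the mean over 1000 random placements (grey bars, with error bars that span the central 95% of the placements); the x axis gives each window in Mb of hg19. The bars of deposited peaks range from 6 at 1q23 to 73 at 6p22, all above the placements.

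In the gene table of GRCh38.p14, the order of genes shows what such clusters hold. On chromosome 6, 98 tRNA genes stand between the histone genes H4C8 and H2BC13, among the butyrophilin genes (BTN3A2, BTN2A1 and others), ABT1 and PRSS16, with 5 more histone genes such as H2BC11 and H4C9. A further 46 follow between the histone gene H2BC17 and ZNF311, among 10 zinc finger genes named ZNF, ZSCAN or ZKSCAN. On chromosome 17, 18 tRNA genes stand between ALOXE3 and PFAS, among PER1, a circadian clock gene, AURKB, a mitotic kinase, and CTC1, a telomere maintenance gene. On chromosome 1, 32 stand between CFAP126 and FCGR3B. On chromosome 7, 19 stand between ZNF783 and KRABD3, and on chromosome 5, 17 stand between BTNL9 and TRIM41. On chromosome 14, 14 stand between RNASE12 and ANG, and on chromosome 16, 14 stand between ZNF213 and ZNF200. The table has another build than the peaks, so none of these genes was matched to a peak.

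Peaks in the windows also scored higher. Their median score was 102, against 68.6 for the 1190 other peaks, a difference of 33.5 (two-sided permutation test, adjusted p = 3e-05). They were 83 bp wider in the median (976.5 against 893.5 bp, adjusted permutation p = 0.0409), and the difference in score held within strata of width (adjusted p = 3e-05). The highest-scoring window peak lay in 17p13, at 8021867 to 8024704 of chromosome 17, with a score of 788. It was followed by 180648436 to 180650000 of chromosome 5 in 5q35, with 312, and 26312489 to 26313772 of chromosome 6 in 6p22, with 294. In 14q11 the highest-scoring peak, at 21080968 to 21082270 of chromosome 14, had 261. In 1q21 it lay at 145398631 to 145399719 of chromosome 1, with 211, and in 16p13 at 3240919 to 3242399 of chromosome 16, with 210 (209.93 in the list). In 7q36 it lay at 149387682 to 149388512 of chromosome 7, with 192, and in 1q23 at 161499656 to 161501418 of chromosome 1, with 151. By median score the windows ranged from 62.6 at 7q36, below the 68.6 of the other peaks, to 201 (200.56) at 5q35. The permutation test treats peaks as independent, so its p does not measure the spread between windows.

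The title also names G-rich DNA. Sequence was not analysed here, and band staining and CpG islands gave 2 coarse readings. Pale Giemsa bands, which are richer in GC and in genes than dark bands, held 805 of 1338 peaks, or 60.2% (95% interval 57.5 to 62.8), against 620.3 by placement (1.30-fold, two-sided permutation p = 0.002, the smallest possible). Peak density was 0.616 per Mb in pale bands and 0.201 per Mb in the darkest. It was 0.488 in the lightest, 0.503 in the middle and 0.264 in the darker of the intermediate classes. With the tRNA windows taken out of both peaks and band lengths, the middle class had 0.339 per Mb, and the pale and darkest bands had 0.560 and 0.201. On chromosomes X and Y, 6 of 75 peaks overlapped a CpG island, or 8% (95% interval 2.99 to 16.6), against 0.818 by placement (7.34-fold, one-sided permutation p = 0.001). One of these was a Y peak that repeats an X peak, and without the repeats 5 of 66 overlapped (6.57-fold, permutation p = 0.001). Scores in pale bands had a median of 74.2, against 65.6 elsewhere (two-sided permutation test, adjusted p = 0.00032). Peaks in pale bands were also wider, with a median of 967 against 857 bp (adjusted permutation p = 3e-05). Within strata of width the difference in score was weaker (adjusted permutation p = 0.0305).

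WRN has known roles in telomere maintenance, and a further comparison asked whether peaks lay near chromosome ends. Within 1 Mb of an end lay 148 peaks, or 11.1% (95% interval 9.43 to 12.9), against 21.4 by placement, a 6.92-fold excess (two-sided permutation p = 0.002, the smallest possible). Of 48 chromosome ends, 37 had at least 1 such peak. The 48 ends were not screened for assembly gaps, where no peak can lie. The 5 peaks at the short-arm end of Y repeat the 5 at that of X in width and score. The long arms of chromosome 5, with 14, chromosome 17, with 8, and chromosome 18, with 7, and the short arm of chromosome 7, with 7, had the most. The 14 on chromosome 5 are those of the 5q35 tRNA window; with all windows taken out of peaks and placements, 134 peaks remained against 19.4, the same 6.92-fold excess. Among the 669 peaks above the median score the excess was 10.4-fold, with 112 peaks. With placement matched on band stain, the 148 peaks stood against 27.57, a 5.37-fold excess. Gene density and GC content were not matched, and no cause of the excess near the ends was tested. Density fell from 3.08 peaks per Mb in the outermost 1 Mb to 2.46 from 1 to 2 Mb, 0.931 from 2 to 5 Mb and 0.396 from 5 to 10 Mb. Farther in it was 0.322. Peaks near the ends were wider, with a median of 1157 against 878 bp (two-sided permutation test, adjusted p = 3e-05). Their median score was 89.1 against 68.2 (adjusted permutation p = 3e-05), but within strata of width the difference missed the threshold (adjusted p = 0.0523).

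By chromosome, 4 of 24 held more peaks than their length predicts and 3 held fewer. Chromosome 17 had 79 peaks against 35.1 by length (2.25-fold, exact binomial test, adjusted p = 1.1e-09). Chromosome 6 had 73 peaks inside and 71 outside the 6p22 window, against 74.0 in all by length (1.95-fold, exact binomial test, adjusted p = 2.0e-12). Chromosomes 19 and 16 had 1.84-fold and 1.46-fold excesses (adjusted exact p = 0.00098 and 0.019). Chromosomes 3, 4 and 9 had 0.631, 0.690 and 0.573 of the expected number (adjusted exact p = 0.0013, 0.010 and 0.0014). With the tRNA windows taken out of both peaks and lengths, chromosome 6 had 71 peaks against 64.9 (adjusted exact p = 0.665), while chromosome 17 kept 72 against 30.98 (adjusted exact p = 2.9e-09). Chromosomes 4 and 16 then also missed the threshold, and chromosome 8, with 77 peaks against 56.5, passed it (adjusted exact p = 0.037). Of these 77 peaks, 13 lay within 99.6 kb in band 8p12, and the test was not repeated without them. The chromosome tests, like the random placements and the score permutations, treat peaks as independent, which clustered peaks are not.

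Among the 20 peaks with the highest scores, 1 lay in a tRNA window, 8 within 5 Mb of a chromosome end and 2 in centromeric or variable bands. The first, at 9825296 to 9828445 of chromosome 21, had the score of exactly 3100 and lay in 21p11.2, on the short arm of an acrocentric chromosome, the arm type that carries the ribosomal RNA gene arrays. The second and the fourth lay in 8p12, the band of the gene that encodes WRN itself, at 30915603 to 30916952, with a score of 2696, and at 30921233 to 30922475, with 1580. The third lay in 1q22, at 156185991 to 156187195 of chromosome 1, with 1726. The fifth lay in the centromeric band 20p11.1, at 26188267 to 26190411 of chromosome 20, with 1451. The sixth lay in 11p15.5, at 1796217 to 1797715 of chromosome 11, with 1398, and the seventh in Xp22.31, at 8136633 to 8138838 of chromosome X, with 1025. The other 13 scored between 580.7 and 926.6. They included peaks within 5 Mb of a chromosome end in 12q24.33, 4q35.2, 18q23, 10p15.3 and 2q37.3, another in 11p15.5, and peaks in 17q12, 5q13.2 and 17q21.2. Exon, intron or untranslated region was not assigned to any peak. The list was not screened here for regions that give high signal in any library. A high score therefore does not by itself mark a site of WRN.

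Band 8p12 held 13 peaks, all within 99.6 kb of its 7.7 Mb, from 30915603 to 31015247 of chromosome 8. No other stretch of that length held as many in the list, the next having 12, in 16p13, and random placement never put more than 4 in one. The peaks were 527 to 1754 bp wide, with a median of 912 bp, close to the 902 bp of the whole list. They stood 2.03 to 16.8 kb apart. The 2 highest, at the low-coordinate end, were 5.58 kb apart and had the scores of 2696 and 1580 given above. The remaining 11 scored from 54.6 to 169 (168.78).

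**Figure D3:**
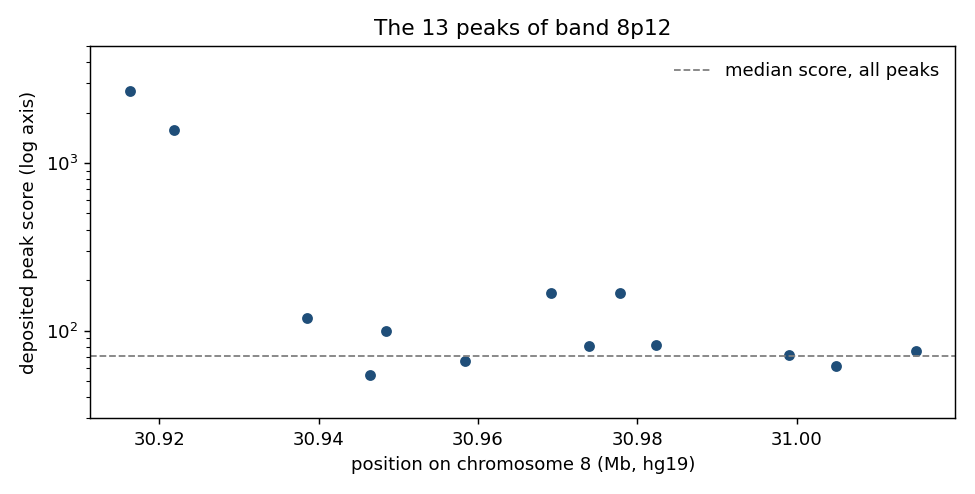
Deposited score (y, log axis) of each of the 13 peaks of band 8p12 against its midpoint (x, Mb of hg19 on chromosome 8); the dashed line is the median score of all 1340 peaks, 70.5. The 2 peaks at the left score 2696 and 1580, and the others lie between 54.6 and 169.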

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

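Every test in this part was chosen after the result was seen, as were the alternatives matched on stain. No comparison used the 2 peaks on hg19 sequences that have a chromosome but no position on it. One was assigned to chromosome 17, with a score of 170 (169.95). The other was assigned to chromosome 1, with 53.9, near the lowest score in the list.

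The peaks of 8p12 stand in the band of the gene whose product was precipitated. A copy gain of the whole band would spread peaks over its 7.7 Mb. All 13 spanned only 99.6 kb, and therefore 0 lay outside a single stretch of 200 kb. This argues against a gain of the whole band, but not against one confined to that stretch. DNA of the WRN gene from outside the chromosome, such as a plasmid, a cDNA or a PCR product handled in the laboratory, needs exactly such a confined set, and 0 peaks outside the stretch is what it predicts. Binding of WRN to its own gene predicts the same 13 of 13 and cannot be told apart from foreign DNA here, because exon positions and reads were not analysed. Peaks at exons with none at the introns between would be a candidate test for a cDNA source, and until then these 13 peaks, with ranks 2 and 4 by score among them, are of uncertain origin.

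The tRNA windows are gene-rich, and several explanations other than binding were weighed. Band stain alone would give no excess over placements matched on stain, yet a 10.72-fold excess remained (permutation p = 0.001). Gene density within bands was not matched, so this value cannot decide whether gene-rich DNA in general accounts for the excess. Copy gains wider than the windows would fill the flanks, which held 9 peaks against 148 inside. At 1q21, however, the left flank held 1 peak and the right flank 4, against 14 inside. The flanks were not screened for assembly gaps, where no peak can lie, so the count cannot decide for that window. Reads shared between tRNA gene copies stay open: 0 pairs of window peaks had equal width and score, although 1 window peak matched a peak outside the windows in both, and copies with different flanks need not give such pairs. Background at highly transcribed RNA polymerase III genes in any precipitation also stays open and was not tested, because no control peak list was used here.

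Of 18 peaks on chromosome Y, 9 had a peak on chromosome X of equal width and score, all at an offset of 50000 bp and all in the terminal band Yp11.32, where they were the only peaks. Scores of the pairs ran from 51.6 to 155. Chance equality of width and score does not account for them, since shuffling the scores among X and Y peaks gave at most 2 pairs in 1000 draws. The 9 pairs are consistent with reads placed at both copies of the pseudoautosomal region, so that each such site is counted in the list more than once. Elsewhere in the list a further 16 pairs, formed by 29 peaks, had equal width and score. Their scores ran from 50.3 to 105, with a median of 53.9, near the lowest in the list. Shuffling the scores over all peaks gave at most 3 pairs in 1000 draws, and at most 7 within strata of width or of score, so chance does not account for most of them. Sites counted more than once may therefore not be limited to the pseudoautosomal region. Whether these 16 pairs come from reads placed at repeated sequence, or from peaks of few reads that come out alike, was not tested. No biological explanation was tested for either set of pairs. Whether the cells carry a Y chromosome was not examined here. No peak listed on Y, in a pair or not, is therefore shown to be a site on that chromosome.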

How the results depend on the processing

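Across 30 alternatives for 8 results, 29 kept their direction and their side of the threshold, or for the count of chromosomes stayed within 1.5 times of it. The exception was the higher score near chromosome ends: the difference of 20.91 had an adjusted p of 0.0523 when permuted within strata of peak width, and the cause was not tested. The excess in the tRNA windows ranged from 10.72-fold, with placement matched on stain, to 22.41-fold in the peaks above the median score. The excess near chromosome ends ranged from 3.74-fold within 5 Mb to 10.4-fold in the peaks above the median score, and that in pale bands from 1.20-fold without peaks near the ends to 1.41-fold. The CpG island excess on X and Y ranged from 5.72-fold to 7.87-fold, on 3 to 5 overlapping peaks. Between 5 and 7 chromosomes passed the test, but only their number was compared, not which they were. Without the tRNA windows, chromosomes 4, 6 and 16 missed the threshold and chromosome 8 passed it, so the set of chromosomes was not stable. The alternatives matched on stain, over whole chromosomes, by midpoint and without the windows were chosen after seeing the data. So were those without the 22 peaks of 8p12 and repeated on Y, and those for the counts in bands and at islands. The chromosome test on length outside centromeric, heterochromatic and stalk bands was also chosen then. The score comparison and its strata of width were fixed in advance for the tRNA windows. For scores near ends and in pale bands, both the comparison and the use of the strata were chosen after seeing the data. Alternatives fixed in advance that need genes, start sites or sequence were not run: gene overlap rules, distances to start sites, gene lists, GC matching, G-quadruplex loops and flanking sequence. No paired analysis was possible because each group has 1 library. With 1 peak list and no read counts, neither the error between cultures nor the effect of another calling threshold below the deposited one can be given.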

Other observations

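Outside the windows and 8p12, the fullest places lay at chromosome ends and were picked out after their values were seen. Band 7q36.3 held 19 peaks, with a median score of 80.5, and 17q25.3 held 16. Bands 13q34 and 2q37.3 held 15 each, with median scores of 130.9 and 79.5, and 18q23 held 14. Band 8p23.3 held 13 in 2.2 Mb. Of the 6 peaks wider than 5 kb, 4 lay within 2 Mb of a chromosome end. The widest, 11706 bp, lay in 14q32.33, at 105695711 to 105707416 of chromosome 14, with a score of 400.5. The others of these 4 were in 12q24.33, 3q29 and 2q37.3, with widths of 7985, 7654 and 5818 bp and scores of 926.6, 152 and 600 (600.26).

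A smaller tRNA cluster of the gene table was not among the fixed windows. On chromosome 11, 8 tRNA genes stand between OR4D9 and OSBP. The peak list held 5 peaks in 11q12.1, all in the bin from 59 to 60 Mb, with a median band score of 149.9. Whether these peaks lie at those genes was not analysed here.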
